A study of Mus musculus with 8 samples.

How the data were processed

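The data were RNA sequencing libraries from whole hearts of mouse embryos at embryonic day 18.5, 4 WT and 4 homozygous for CHD4 M195I. RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCm38 (also named mm10), and counted per gene with featureCounts of Subread 1.5.2, per the submitters' processing notes. The deposited values are raw counts per gene, 1 file per library and a series-wide table, and no value differed between these sources. The column headers of the files per library begin with "Male", per the file headers. The strand setting of the counting and the annotation release are not given in the sources used here. The files held 49315 genes. Symbols were taken from GENCODE M21, which gave one to 48970 of them, and 91.44% of the genes found in that release had the same position there. Coordinates are those of the count files on GRCm38.

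Genes were kept by filterByExpr with the genotype (minimum count 10), which left 16372. Library sizes were scaled by TMM, with factors from 0.963 to 0.993 in WT and from 1.01 to 1.03 in the mutants. Genotypes were compared with the robust quasi-likelihood fit and test of edgeR 4.0.16 in R 4.3.3, with no covariate, and called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.0908. Standard errors of log2 fold changes come from the same fit. Levels in CPM are per library and scaled by TMM, except those of airway and lung, Y-linked and Xist transcripts, which use library totals. Replicates were checked for repeats of the same library: the chi-square per degree of freedom between pairs within a genotype ranged from 2.88 to 9.29.

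The 42 gene lists, the model, the rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Beside it stood camera with an estimated correlation, fry, and the number of called members, adjusted over all genes and over the list alone. Called genes within 5 Mb of Chd4 were compared with the rest by a two-sided Fisher's exact test. Principal components used log2 CPM of the 500 most variable genes. Named genes were the 10 with the largest change in each direction among called genes with a mean of at least 1 CPM and no overlap between the genotypes, the 5 with the smallest adjusted p, and up to 2 called members per list and direction by adjusted p. Symbols made of Gm and digits or ending in Rik or -ps, genes without a symbol, Xist and Y-linked genes were left out of the first 2 groups. Chd4, Adamts1, Smarca4, Nppa, Nppb, Myh6 and Myh7 were always named. A gene that this rule selects is not reported here. Other genes named are markers of tissue or sex, genes whose exons overlap, or members of the sets in the closing section.

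The gene test was tested on simulated counts in which 200 genes were changed before the filter, and 16101 genes passed it. Among those, it recovered 44.0% of genes changed 1.25-fold, 58.3% of those changed 1.5-fold, 81.6% of those changed 2-fold and 87.8% of those changed 3-fold, and 4.32% of its calls were unchanged genes. On simulated lists over the 16372 genes, camera called 0 of 40 unchanged and 2 of 2 changed lists. Genes were simulated independently of each other, so this does not measure false list calls where genes move together. Fewer genes were changed than the 2168 called in the data, and the Benjamini-Hochberg threshold depends on that number. The shares recovered need not hold for the data. The alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, library totals, upper quartile), other filters and thresholds, a fit that is not robust, each library left out in turn, the replicate number as a block, Xist as a covariate, removal of mitochondrial and haemoglobin genes, and the series-wide table. Those added after the data were examined were a lung epithelium score as a covariate, fits within the libraries with and without airway RNA, and a correction for gene length and GC content. The genotypes were also refitted under all 35 ways of splitting the 8 libraries 4 against 4.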

Results

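The data were RNA sequencing counts from whole hearts of mouse embryos (Mus musculus) late in gestation (E18.5). The 4 mutant hearts were homozygous for the M195I change in CHD4, per the labels, and the other 4 were wild type (WT). CHD4 is the chromatin-remodelling ATPase of the nucleosome remodelling and deacetylase (NuRD) complex. The labels give each library as a separate sample, numbered 1 to 4 within its genotype, without naming a litter or batch. Total counts per library ranged from 18375951 to 20815388 in WT and from 18673488 to 21341235 in the mutants. The comparison asks which transcripts differ in level between the mutant and WT hearts. Levels are in CPM scaled by TMM unless stated otherwise, as mean ± SD with n = 4 per genotype. Log2 fold changes are mutant minus WT with their standard errors, and adjusted p-values come from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment. They measure the spread between these samples, since the labels do not say that each heart came from a different litter.

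The mutant hearts had lower levels of transcripts for glycolysis, the response to hypoxia, immediate early factors and the sarcomere, and higher levels of transcripts for DNA replication. With an estimated correlation the tests of these lists did not pass (adjusted p = 0.27, 0.33, 0.27 and 0.40, and 0.27 for DNA replication), and the statement rests on their called members and on fry. Over the 35 splits of the libraries, the median of each of these lists was largest in size in the real split. The permutation p from these splits, adjusted over the lists, was 0.11 for each and did not pass. Of 16372 genes tested, 942 were higher and 1226 lower in the mutants. Most differences were small: the median size over the called genes was 0.27 on the log2 scale, and 31 higher and 39 lower genes differed by a log2 fold change of at least 1. The levels of the 4 mutant and 4 WT libraries did not overlap for 1988 of the 2168 called genes, and 18.6% of all tested genes had no overlap where chance gives 2.86%. With library totals in place of TMM, 1856 genes were higher and 858 lower, so the share of higher genes among the calls moved from 43.5% to 68.4%. Without WT replicate 1, 579 genes were called higher. With Xist as a covariate, which is itself higher in most mutant libraries, 117 genes were higher and 149 lower, and 11.3% of the calls were kept.

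**Figure D1:**
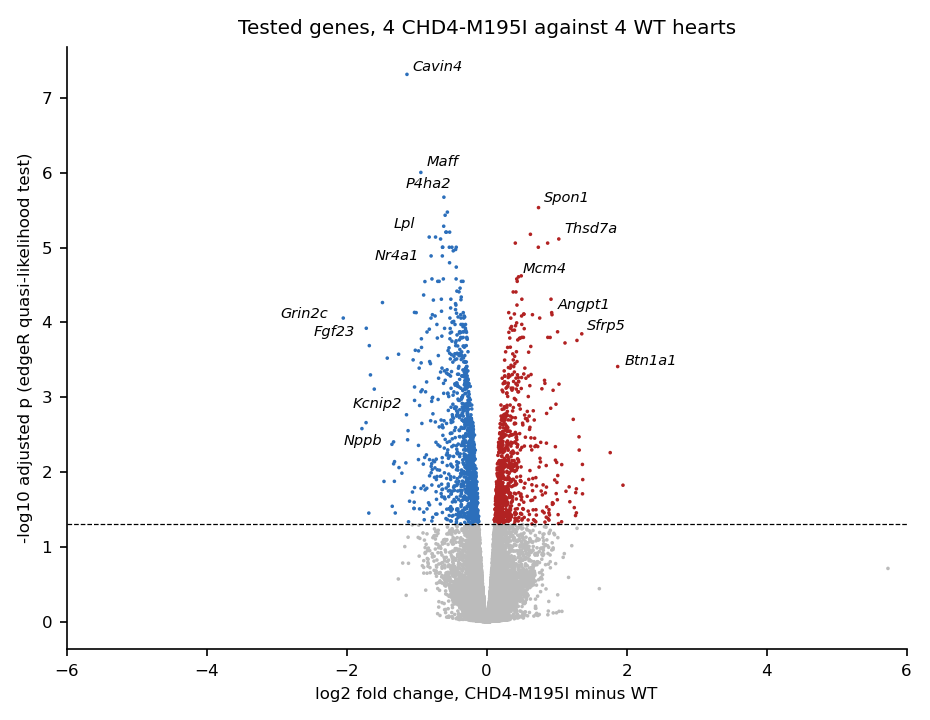
Each point is 1 of the 16372 tested genes, with the log2 fold change (mutant minus WT) on the x axis and -log10 of the edgeR adjusted p on the y axis. The dashed line is the threshold of 0.05, red points are the 942 genes higher and blue points the 1226 lower in the mutants, and Cavin4 has the smallest adjusted p.

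Chd4 itself (chromosome 6, 125095981 to 125130591, GRCm38) had a mean of 452 ± 6.37 CPM in WT and 482 ± 8.48 CPM in mutant hearts. This was a log2 fold change of 0.09 ± 0.03 that did not pass the threshold (adjusted p = 0.094), although the lowest mutant library lay above the highest WT library. The DESeq2 test put it past the threshold (adjusted p = 0.0089), as did library totals (0.14, adjusted p = 0.0063). The counts do not show the base at the mutated codon, so they give no check of genotype. Within 5 Mb of Chd4, 13 of 125 tested genes were called, against 2155 of 16247 elsewhere (odds ratio 0.76, 95% interval 0.39 to 1.35, Fisher's exact test, two-sided p = 0.43). Without WT replicate 4 the odds ratio was 1.07. Fgf23 (127072902 to 127081408, -1.72) and Clec7a (129461591 to 129472779, 1.32), named below among the largest changes, lie within 5 Mb of Chd4. For these genes an effect of sequence linked to Chd4 was not told apart from an effect of the mutation.

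Libraries differed more in transcripts of airway epithelium than by genotype. The first principal component of the 500 most variable genes held 90.0% of the variance and followed these transcripts, whereas the second, with 3.28%, separated the genotypes. Scgb3a2, a secretoglobin of airway epithelium, lay between 176 and 498 CPM of the library totals in WT replicates 1, 3 and 4 and mutant replicates 3 and 4, and between 0.328 and 6.48 CPM in the other 3 libraries. Sftpc, a surfactant protein gene of alveolar cells, reached 124 CPM in mutant replicate 4 and at most 4.08 CPM elsewhere. Over the 13 tested members of the lung epithelium list, 1 fell (Etv5, a call lost without any 1 of 7 libraries; none adjusted over the list alone) and 12 were not called, with a median log2 fold change of 0.05, a mean of 0.60 and a camera direction of down (adjusted p = 0.37). The lung list passed as lower without WT replicate 2 (median -0.26, adjusted p = 0.0070). Haemoglobin genes took 0.279 ± 0.091% of the counts in WT and 0.156 ± 0.029% in mutant hearts. The list of 15 erythroid markers was not called (median -0.28, adjusted p = 0.31). It passed without WT replicate 2 (-0.37, adjusted p = 0.017) or mutant replicate 1 (-0.39, adjusted p = 0.043). In the 5 libraries with Scgb3a2 of at least 10 CPM, 609 genes were higher and 1062 lower, and in the other 3 libraries, where WT has 1 library, 595 were higher and 812 lower. With the mean log2 CPM of the lung epithelium list as a covariate, 1238 genes were higher and 1633 lower.

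**Figure D2:**
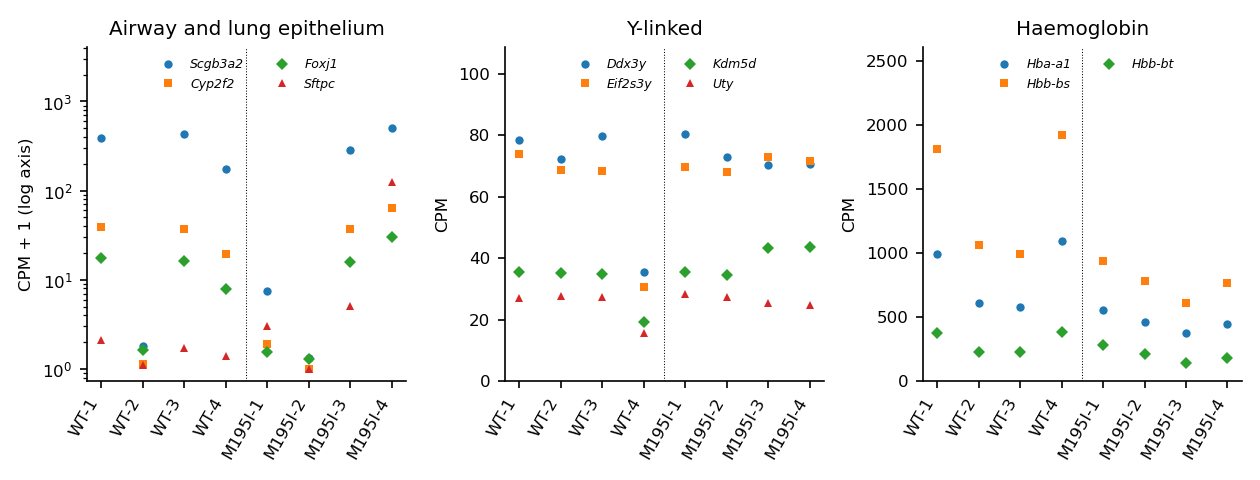
CPM of the library totals (y axis) in each of the 8 libraries (x axis) for transcripts of airway and lung epithelium (left, CPM + 1 on a log axis), Y-linked genes (middle) and haemoglobin genes (right). Scgb3a2 is high in 5 libraries of both genotypes, the 4 Y-linked genes are lowest in WT replicate 4, and the dotted line parts WT from mutant libraries.

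The gene with the smallest adjusted p was Cavin4, a muscle caveolar protein, at 63.1 ± 1.66 CPM in WT and 28.7 ± 2.26 CPM in mutant hearts (-1.14 ± 0.06, adjusted p = 4.8e-08). The next were the bZIP factor Maff (-0.94 ± 0.06, adjusted p = 9.9e-07), the collagen prolyl hydroxylase P4ha2 (-0.61 ± 0.04, adjusted p = 2.1e-06), Spon1, a secreted matrix protein (0.74 ± 0.05, adjusted p = 2.9e-06), and Frmd5 (-0.56 ± 0.04, adjusted p = 3.4e-06). By size, among called genes with a gene symbol, a mean of at least 1 CPM and no overlap between the genotypes, those that fell most were Grin2c (-2.05 ± 0.24), Fgf23 (-1.72 ± 0.21), the mitochondrial tRNA gene mt-Ti (-1.68 ± 0.18), the cholesterol hydroxylase Ch25h (-1.66 ± 0.25), the nicotinamide riboside kinase Nmrk2 (-1.49 ± 0.11), mt-Tq (-1.42 ± 0.19), the natriuretic peptide gene Nppb (-1.33 ± 0.17), Ddn (-1.32 ± 0.27), Fam180a (-1.32 ± 0.29) and Tceal7 (-1.26 ± 0.15). Under the same conditions, those that rose most were Btn1a1 (1.87 ± 0.27), the Wnt-binding Sfrp5 (1.36 ± 0.17), Clec7a (1.32 ± 0.26, annotated as a polymorphic pseudogene), Slitrk5 (1.29 ± 0.16), Car4 (1.28 ± 0.31), Oprd1 (1.24 ± 0.22), Tnfsf10 (1.12 ± 0.15), Ddx60 (1.03 ± 0.16), Thsd7a (1.03 ± 0.09) and Fgfr4 (1.03 ± 0.32). Adjusted p-values of these 20 genes lay between 7.7e-06 and 0.049. Most of the genes that rose were scarce, with mutant means from 1.36 CPM (Fgfr4) to 22.7 CPM (Thsd7a). Some that fell were scarce too, with WT means of 1.66 (Fam180a), 3.33 (Grin2c), 3.48 (Fgf23) and 3.51 CPM (Ch25h). Others that fell were not, such as Nppb at 338 CPM and Nmrk2 at 53.2 CPM in WT. Fgfr4 lost its call without any 1 of 7 libraries and stood at 0.63 without mutant replicate 4, and Car4 lost its call without WT replicate 2 (adjusted p = 0.057). Exons of Nmrk2, Tceal7, Ch25h, Ddn, Grin2c, mt-Ti and mt-Tq overlap those of another annotated gene, and the strand setting of the counting is not given in the sources used here, so their counts may hold reads of the neighbour.

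**Figure D3:**
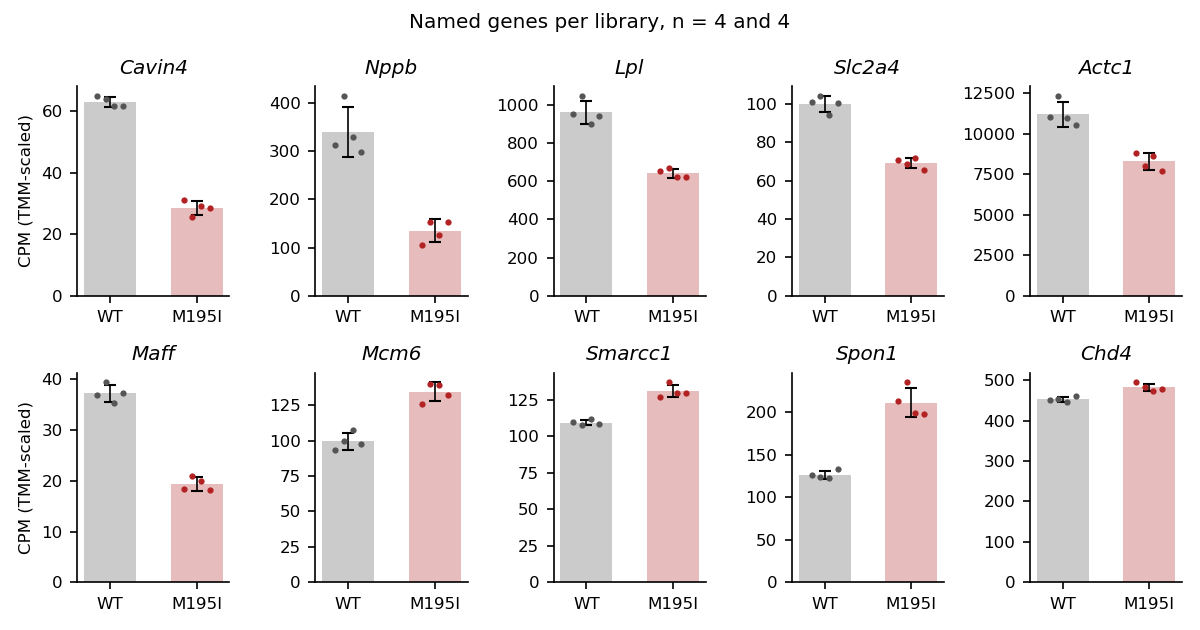
Levels of 10 named genes in CPM scaled by TMM (y axes) in WT and mutant (M195I) hearts, with bars for means, error bars for SD (n = 4) and points for libraries. In each panel the 4 mutant libraries lie on one side of the 4 WT libraries, including Chd4, whose log2 fold change of 0.09 did not pass the threshold.

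Genes were also read by 42 lists fixed beforehand. Camera, with a preset inter-gene correlation of 0.01, called 2 lists higher and 12 lower. No list was called with an estimated correlation, and 26 of the 35 ways of splitting the 8 libraries, the real one included, gave at least as many camera calls. The counts of called members and fry, a test of whether a list's genes move one way, therefore carry the statements on lists. Fry does not ask whether a list stands out from other genes. Over the splits, 11 lists had their largest median in size in the real one. Their permutation p, adjusted over the 42 lists, was 0.11, the smallest of any list. With 35 splits no list could pass alone. Fry called 10 lists, all among the 14. Adjusted p-values of lists below are from camera unless fry is named.

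**Figure D4:**
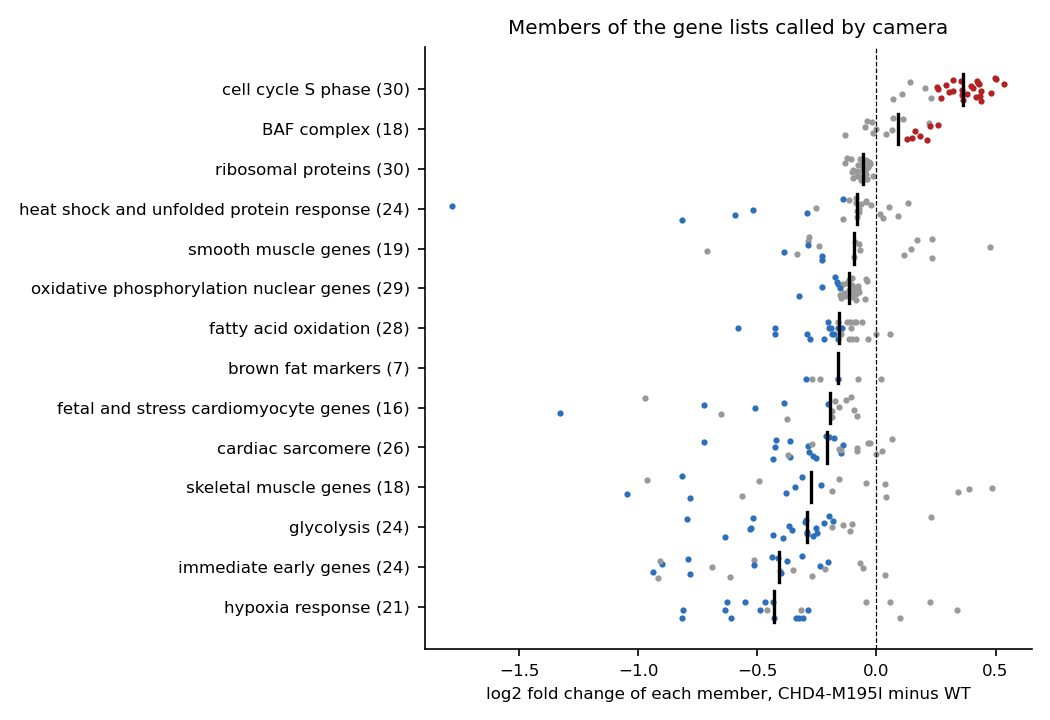
Log2 fold change (x axis, mutant minus WT) of each tested member of the 14 lists called by camera, with the number of members in parentheses. Red and blue points are members called higher and lower, grey points were not called, and black bars are list medians, from -0.43 in the hypoxia response to 0.36 in the S phase of the cell cycle.

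Transcripts for DNA replication rose in the mutant hearts. Of 30 S phase genes, 25 rose and none fell (27 rose adjusted over the list alone), with a median log2 fold change of 0.36 (adjusted p = 4.3e-20, fry adjusted p = 0.0053). With an estimated correlation the adjusted p was 0.27. The replicative helicase subunits Mcm4 (54.8 ± 1.75 CPM in WT, 73.8 ± 2.75 CPM in mutants, 0.43 ± 0.04) and Mcm6 (0.43 ± 0.05) were among them. The 30 genes of G2 and M phase were not called as a list (median 0.07, adjusted p = 0.32), although the list passed without mutant replicate 1 (0.13, adjusted p = 4.4e-05). Over all genes 1 of them fell and adjusted over the list alone none did. This was Ube2c (-0.22 ± 0.06, adjusted p = 0.022), whose exons overlap those of the muscle gene Tnnc2 and whose call was lost without WT replicate 2, 3 or 4 or mutant replicate 3 (adjusted p from 0.052 to 0.073). Among 25 cell cycle inhibitors and p53 targets, 4 rose and 3 fell (5 and 3 adjusted over the list alone), and the list was not called (median -0.02, mean 0.03, direction up, adjusted p = 0.97). The pocket protein Rbl1 rose (0.40 ± 0.06), as did the CDK inhibitor Cdkn1c (0.22 ± 0.04), and Cdkn1a fell (-0.18 ± 0.04). The 5 tested replication-dependent histone genes were not called (median 0.00, mean -0.01, direction down, adjusted p = 0.89). Of 17 imprinted growth genes, 5 rose (5 rose and 1 fell adjusted over the list alone), with Plagl1 at 0.27 ± 0.05, and the list was not called (median 0.05, adjusted p = 0.14), although it passed without mutant replicate 4 (0.07, adjusted p = 0.039).

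Subunits of the BAF chromatin-remodelling complex were slightly higher in the mutants: 7 of 18 rose and none fell (9 rose and 1 fell adjusted over the list alone). The median was 0.09 (adjusted p = 0.00095, fry adjusted p = 0.0053, and adjusted p = 0.27 with an estimated correlation). Smarcc1 (0.26 ± 0.04, adjusted p = 0.00032) and Smarce1 (0.22 ± 0.03, adjusted p = 0.00056) rose, with exons of Smarcc1 overlapping those of Dhx30, and the ATPase Smarca4 was at 0.11 ± 0.04 (adjusted p = 0.052). Of 15 NuRD subunits, Chd3, the paralogue of Chd4, fell (-0.23 ± 0.05, adjusted p = 0.0085) and Hdac1 rose (0.12 ± 0.04, adjusted p = 0.042), a call that was lost without any 1 of 7 libraries. The NuRD list was not called (median 0.03, adjusted p = 0.53; 2 rose and 1 fell adjusted over the list alone).

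Many transcripts for glucose and fatty acid use were lower in the mutant hearts. Of 24 glycolysis genes, 19 fell and none rose (21 fell adjusted over the list alone), with a median of -0.29 (adjusted p = 5.7e-17, fry adjusted p = 0.0053). The adjusted p was 0.27 with an estimated correlation. The insulin-responsive glucose transporter Slc2a4 went from 99.8 ± 4.23 to 69.2 ± 2.80 CPM (-0.53 ± 0.04, adjusted p = 6.2e-06), and the phosphofructokinase Pfkp, whose exons overlap those of Pitrm1, fell alike (-0.53 ± 0.05). In the hypoxia response list, which shares 2 genes with glycolysis, 14 of 21 fell and none rose (16 fell and 1 rose adjusted over the list alone), with a median of -0.43 (adjusted p = 2.3e-10, fry adjusted p = 0.0070, and adjusted p = 0.33 with an estimated correlation). P4ha2 and the oxygen sensor Egln1 (-0.32 ± 0.04) were among them. Of 28 genes for fatty acid oxidation and uptake, 14 fell and none rose (15 fell adjusted over the list alone), with a median of -0.16 (adjusted p = 2.5e-08, and adjusted p = 0.55 with an estimated correlation). The lipase Lpl, at 960 ± 61.5 CPM in WT and 641 ± 24 CPM in mutants (-0.58 ± 0.05), and the acyl-CoA synthetase Acsl1 (-0.42 ± 0.04) fell. Of 29 nuclear genes for oxidative phosphorylation, 6 fell (12 adjusted over the list alone) and all 29 had a negative log2 fold change, with a median of -0.11 (adjusted p = 9.8e-08, and adjusted p = 0.70 with an estimated correlation). Cox8b (-0.33 ± 0.06) and Sdhb (-0.23 ± 0.05) were lower. Fry did not call either of the last 2 lists (adjusted p = 0.056 and 0.14). In 2 of the 35 splits, the real one included, the median of the fatty acid oxidation list was at least as large in size. Among 7 tested brown fat markers, Fabp4 (-0.29 ± 0.04) and Cox7a1 (-0.16 ± 0.05, a call lost without any 1 of 6 libraries) fell (2 also adjusted over the list alone), with a median of -0.16 (adjusted p = 0.032, fry adjusted p = 0.0092, and adjusted p = 0.27 with an estimated correlation). The camera call was lost without mutant replicate 3 or 4 (adjusted p = 0.065 and 0.057), and 1 of the 7, Cox7a1, is also in the oxidative phosphorylation list.

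The 13 tested mitochondrial protein-coding genes moved apart. mt-Cytb (0.22 ± 0.05) and mt-Nd5 (0.18 ± 0.04) were among 3 that rose, and mt-Nd3 (-0.66 ± 0.12) and mt-Nd4l (-0.70 ± 0.09) among 3 that fell, with the same counts adjusted over the list alone. The 3 that fell were far scarcer in WT: mt-Nd3 at 82.9 CPM, mt-Nd4l at 11.96 CPM and mt-Co3 at 9.17 CPM. Those that rose were at 2241 CPM (mt-Nd4), 5065 CPM (mt-Nd5) and 6964 CPM (mt-Cytb) in WT. Whether the counts of the 3 that fell follow their transcripts was not tested. The list was not called (median 0.09, mean -0.06, direction up, adjusted p = 0.92). Exons of mt-Nd4l overlap those of mt-Nd4, and those of mt-Nd5 overlap mt-Nd6. Mitochondrial genes took 4.64 ± 0.18% of the counts in WT and 4.89 ± 0.072% in mutants.

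Called members of the cardiac, skeletal and smooth muscle lists were all lower, and many members were not called. Of 26 cardiac sarcomere genes, 15 fell and none rose (18 fell adjusted over the list alone), with a median of -0.21 (adjusted p = 1.9e-10, fry adjusted p = 0.019, and adjusted p = 0.40 with an estimated correlation). The cardiac actin Actc1 went from 11206 ± 775.3 to 8288 ± 516.4 CPM (-0.44 ± 0.06), and the intermediate filament desmin, Des, fell by 0.36 on the log2 scale. Myh6 (-0.37 ± 0.12, adjusted p = 0.096) and Myh7 (-0.16 ± 0.06, adjusted p = 0.076), the cardiac myosin heavy chains, did not pass. Myh6 passed without mutant replicate 3 (-0.50, adjusted p = 0.00015), and Myh7 passed without WT replicate 3 (adjusted p = 0.034). These myosins, and the actins, are close paralogues that can share reads, and Myh7 overlaps the antisense gene Mhrt. Of 16 fetal and stress genes of cardiomyocytes, 5 fell and none rose (9 fell adjusted over the list alone), with a median of -0.20 (adjusted p = 3.4e-07, fry adjusted p = 0.0053, and adjusted p = 0.27 with an estimated correlation). Nppb went from 338 ± 51.8 to 135 ± 23.6 CPM, the calcineurin regulator Rcan1 fell (-0.39 ± 0.05), and Nppa did not pass (-0.13 ± 0.11, adjusted p = 0.53). Of 18 skeletal muscle genes, 7 fell and none rose (7 also adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0026, fry adjusted p = 0.0097, and adjusted p = 0.27 with an estimated correlation). The calcium-binding Casq1 fell most clearly (-1.05 ± 0.10), and the creatine kinase Ckm fell too (-0.23 ± 0.05). Of 19 smooth muscle genes, 4 fell and none rose (5 fell adjusted over the list alone), among them Myl9 (-0.39 ± 0.05) and Tpm2 (-0.29 ± 0.04), with a median of -0.09 (adjusted p = 0.032, fry adjusted p = 0.16, and adjusted p = 0.70 with an estimated correlation). That call was lost without WT replicate 3 or 4 or mutant replicate 2 (adjusted p from 0.067 to 0.28). In 16 of the 35 splits, the real one included, the median of the smooth muscle list was at least as large in size.

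Genes tied to heart regions moved both ways. Of 22 trabecular genes, 5 rose and 2 fell (9 and 3 adjusted over the list alone), and the list did not pass (median 0.14, mean 0.04, adjusted p = 0.0501). It passed without WT replicate 2 (adjusted p = 0.040) or mutant replicate 3 (0.032) or 4 (0.0092). Cpne5 (0.60 ± 0.09) and Sphkap (0.48 ± 0.06) rose, whereas Nppb and the growth factor Bmp10 (478 ± 71.3 to 249 ± 45.4 CPM, -0.94 ± 0.17) fell. Of 17 atrial genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; median just under 0, mean 0.02, direction up, adjusted p = 0.75), with the angiopoietin Angpt1 at 0.93 ± 0.09 and the nuclear receptor Nr2f2 at 0.27 ± 0.05. Of 12 ventricular genes, Cox6a2 (-0.33 ± 0.07) and Myl3 (-0.21 ± 0.05), whose exons overlap those of Itgad and Pth1r, fell (1 rose and 4 fell adjusted over the list alone; median -0.05, adjusted p = 0.53). Of 18 compact myocardium genes, Gpc3 rose (0.27 ± 0.05) and Igf1r fell (-0.34 ± 0.06), also adjusted over the list alone (median 0.03, adjusted p = 0.56). Among 32 genes of ion channels and calcium handling, 4 rose and 5 fell (5 and 8 adjusted over the list alone; median -0.03, mean just over 0, direction down, adjusted p = 0.58). The pacemaker channel Hcn4 (0.61 ± 0.09) and the calcium channel subunit Cacnb2 (0.25 ± 0.04) rose, and the potassium channel partner Kcnip2 (-0.96 ± 0.11) and the calcium sensor S100a1 (-0.28 ± 0.05) fell. Of 24 cardiac transcription factors, 1 fell, Tbx3 (-0.29 ± 0.08, adjusted p = 0.023), a call lost without WT replicate 1, 2 or 4 or mutant replicate 2 or 3, and 0 were called adjusted over the list alone (median 0.03, adjusted p = 0.70).

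Immediate early genes were lower in the mutants: 12 of 24 fell and none rose (18 fell adjusted over the list alone), with a median of -0.41 (adjusted p = 1.1e-12, fry adjusted p = 0.0053). The adjusted p was 0.27 with an estimated correlation. Maff and Nr4a1 (33.8 ± 1.97 to 19.5 ± 2.08 CPM, -0.79 ± 0.07) had the smallest adjusted p-values in the list. Of 24 genes for heat shock and the unfolded protein response, 6 fell and none rose (6 also adjusted over the list alone), with a median of -0.08 and a mean of -0.21 (adjusted p = 0.0035, fry adjusted p = 0.022, and adjusted p = 0.43 with an estimated correlation). The amino acid response genes Asns (-0.82 ± 0.10) and Atf4 (-0.29 ± 0.05) were among them. All 30 ribosomal protein genes had a negative log2 fold change and none was called, over all genes or adjusted over the list alone (median -0.06, adjusted p = 0.0013, fry adjusted p = 0.36, and adjusted p = 0.96 with an estimated correlation). With library totals the call was lost (adjusted p = 0.10), as it was without WT replicate 2 (0.080) or mutant replicate 3 (0.065). In 6 of the 35 splits, the real one included, the median of the ribosomal list was at least as large in size. The 23 interferon response genes held no called member (median 0.23, adjusted p = 0.31), and this list passed without mutant replicate 1 (median 0.38, adjusted p = 8.6e-08).

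The remaining lists were not called, and their called members went both ways in 6 of them. Among 39 matrix proteases and inhibitors (median -0.04, adjusted p = 0.47), 5 rose and 6 fell, the same counts as adjusted over the list alone. Adamts1, a secreted protease, went from 134 ± 6.44 to 108 ± 4.61 CPM (-0.31 ± 0.04, adjusted p = 0.00033), Adam19 fell (-0.64 ± 0.06), and Adamts17 (0.53 ± 0.08) and Adamts7 (0.31 ± 0.06, with exons overlapping those of Tbc1d2b) rose. Of 48 extracellular matrix genes (median -0.03, adjusted p = 0.29), Col15a1 rose (0.29 ± 0.06) and 5 fell, among them Tnc (-0.39 ± 0.07) and Ogn (-0.44 ± 0.09), with the same counts adjusted over the list alone. The matrix list passed as lower without WT replicate 2 (-0.07, adjusted p = 0.00050). Of 22 endothelial and endocardial markers (median -0.05, adjusted p = 0.31), 1 rose and 7 fell (1 and 8 adjusted over the list alone), with the receptor Tek at 0.20 ± 0.04 and Flt1 at -0.32 ± 0.05. Of 20 fibroblast markers, 1 rose and 3 fell, also adjusted over the list alone, among them Meox1 (-0.42 ± 0.07) and Tcf21 (-0.25 ± 0.05). The fibroblast list had a median of 0.01, a mean of -0.02 and a camera direction of down (adjusted p = 0.84). Of 18 epicardial markers (median -0.13, adjusted p = 0.16), 2 rose and 4 fell (2 and 6 adjusted over the list alone), with Tbx18 at 0.48 ± 0.09 and Upk1b at -0.48 ± 0.08. Of 14 pericyte markers (median -0.06, adjusted p = 0.16), 4 fell, also adjusted over the list alone, among them Cspg4 (-0.33 ± 0.04). Of 14 valve and cartilage genes (median 0.02, mean -0.06, direction down, adjusted p = 0.70), 1 rose and 3 fell (2 and 4 adjusted over the list alone), with Scx, a tendon and valve factor, at -0.85 ± 0.11. Of 21 macrophage markers (median 0.04, adjusted p = 0.32), Lyz2 (0.54 ± 0.10) and Cx3cr1 (0.48 ± 0.12) rose, also adjusted over the list alone, and the list passed without mutant replicate 2 (0.11, adjusted p = 0.046). Of 20 markers of neural crest, Schwann cells and neurons (median -0.01, adjusted p = 0.84), 1 fell, Uchl1 (-0.18 ± 0.05), a call lost without WT replicate 3 or 4 or mutant replicate 1 or 4. No member was called among 8 neutrophil markers (median 0.07, adjusted p = 0.98), 9 liver markers (median 0.20, adjusted p = 0.75), 5 thymus and T cell markers (median -0.10, mean 0.04, direction up, adjusted p = 0.81) and 5 sex-linked transcripts (median 0.17, adjusted p = 0.29).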

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

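The tests of the cardiomyocyte genes, the abundant mitochondrial transcripts and the splits with fry were chosen only after the result was seen. Within each genotype, each named gene, Y-linked gene and marker was examined for a sample far from the other 3, and 18 of 234 groups held one, where chance flags about 1 in 20 groups. In WT replicate 4, Phlda3 lay high at 56.3 CPM (others 53.3 to 53.7), Ch25h low at 2.06 CPM (3.95 to 4.03), and the Y-linked Eif2s3y at 30.5 CPM (68.5 to 73.9), Kdm5d at 19.2 CPM (34.9 to 35.4) and Uty at 15.5 CPM (27.2 to 27.7) were low. In WT replicate 2, Cox7a1 at 126 CPM (110 to 113), Nmrk2 at 66.2 CPM (46.9 to 50) and Myl3 at 2780 CPM (2449 to 2458) were high and Adamts17 at 11.4 CPM (13.9 to 14.4) was low. In WT replicate 1, Xist was high at 1.56 CPM (1.252 to 1.297), and in WT replicate 3, Tbx3 was low at 22.4 CPM (27.0 to 27.2). In mutant replicate 4, Sftpc at 124 CPM (0 to 4.08), Col11a1 at 26.0 CPM (17.5 to 17.9) and Fgfr4 at 2.35 CPM (0.951 to 1.08) were high, and Esam at 59.3 CPM (63.2 to 63.5) and Efemp1 at 16.4 CPM (19.9 to 20.2) were low. In mutant replicate 3, Casq1 was high at 47.6 CPM (37.4 to 39.1), and in mutant replicate 2, Acsl1 was high at 309 CPM (278 to 281).

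The number of called genes was weighed against chance and airway RNA. Of the 35 splits, 1, the real one, gave as many calls as 2168, and the highest other gave 192, in the split that set 4 of the 5 libraries with airway RNA against the rest. With the lung epithelium score as a covariate, 99.6% of the calls stayed in the same direction. The score overlapped between the genotypes (0.60 to 3.95 in WT, 0.42 to 5.17 in mutants), so adjusting for it could remove few calls. The share kept is thus a weak test, which shows only that this score alone did not account for the calls. In the 5 libraries with airway RNA, with fewer samples, 62.5% of the calls were kept. For the number of lists called by camera, 26 of 35 splits, the real one included, gave at least as many (highest other 23), so chance is not excluded for that number. With fry, 1 of 35 splits, the real one, gave as many lists (highest other 0). Fry asks whether a list's genes move one way, without setting them against other genes, and 32 of the other splits called 0 genes. The fry count over the splits is therefore not separate from the count of called genes. That count adds no support for single lists, which rest on their own fry tests and called members. Litter, dissection and library batch, which the labels do not give, stay open beside the genotype.

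The fall of sarcomere and metabolic genes was weighed against fewer cardiomyocytes and against gene length and GC bias. Over 24 cardiomyocyte genes outside those lists the median log2 fold change was -0.028 (bootstrap 95% interval -0.08 to 0.06, with 1 higher and 4 lower). This lay above the sarcomere median of -0.21, so these genes did not fall as much as the sarcomere genes. The interval resamples genes and not hearts, so it does not measure the spread between samples. The test therefore does not decide whether the share of cardiomyocytes was lower. With length and GC corrected, the lists kept from 85.7% (fatty acid oxidation) to 95.5% (sarcomere) of their medians and stayed called by camera with the preset correlation. Without the correction, none of them was called with an estimated correlation, and fry did not call fatty acid oxidation. The share of cardiomyocytes and the genotype, litter and exact stage of each embryo were not told apart by any test and stay open.

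Short mitochondrial features were lower: 19 of 22 of at most 400 bases fell, with a median log2 fold change of -0.67. The 187 tested nuclear genes of at most 400 bases had a median of 0.0057 (bootstrap 95% interval -0.06 to 0.04), so as a set they did not fall. The interval resamples genes and not libraries. The 19 mitochondrial tRNA genes have 59 to 75 bases, so this comparison does not decide on a loss of RNA of that size. The 7 abundant mitochondrial protein-coding genes had a median of 0.092, with 3 higher, which argues against less mitochondrial RNA. The genotype, litter and library preparation were not told apart by any test and stay open.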

How the results depend on the processing

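The lung epithelium covariate, the subsets by airway RNA and the correction for length and GC were chosen only after the result was seen. Of 2534 values of named genes under alternatives, 2319 kept their direction and side of the threshold, 192 lost the call, 22 gained it and 1 reversed. Where no reason is given below, the cause was not tested. Chd4 passed with DESeq2 (0.093) and library totals (0.14). Genes higher were 1856 with library totals, which moves every gene up, and 392 (644 lower) at an adjusted p under 0.01, 1427 at 0.1, and 31 (39 lower) with a log2 fold change of 1 or more. Leaving out 1 library, genes higher ranged from 579 to 850, lists higher from 2 to 4 and the odds ratio near Chd4 from 0.74 to 1.07, reversed without WT replicate 4, with fewer samples in each. Lists higher were 4 without the filter, 4 under the replicate block, 6 with the Xist covariate, 5 in the libraries with airway RNA and 6 in those without, and lists higher and lower were 0 and 0 with an estimated correlation.

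With the Xist covariate 117 genes were higher and 149 lower. Xist was low in all libraries and lay higher in most mutant ones (log2 of CPM plus 1 from 1.17 to 1.36 in WT and from 1.35 to 1.57 in mutants), so the covariate shares the comparison. Nppa (0.076), the liver list (-1.57) and the interferon list (-0.28) reversed under it, the lists by camera direction and median. In the libraries with airway RNA 609 genes were higher, and in those without, 595 were higher and 812 lower, with fewer samples in each. The camera direction of the lung list turned in the former (median 0.71), and that of the matrix (0.11), mitochondrial genome (-0.12) and fibroblast (0.18) lists in the latter, where WT has 1 library. The medians of the lung and fibroblast lists kept their sign. Replicate numbers were not taken to pair the samples, since the labels do not say that they do. Same-number correlations were -0.52, 0.77, 0.56 and 0.10, and not every sample correlated best with its own number. WT replicate 1 correlated positively with mutant replicates 3 and 4, and WT replicate 2 with mutant replicates 1 and 2. These libraries part in the same way by airway RNA, so the correlations cannot decide on a shared litter or batch. A block on the replicate numbers called 1023 genes higher and 1432 lower. At this depth and with 4 libraries per genotype, the test recovered 44.0% of the smallest changes simulated.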

Other observations

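The tests of isoform ratios were chosen only after the result was seen. Counts on most short features of the mitochondrial genome were lower in the mutant hearts. These counts do not tell mature tRNAs from longer RNAs that cover the same bases. Of 19 tested mitochondrial tRNA genes, 17 fell and none rose, with a median log2 fold change of -0.67. Among the more abundant, mt-Tn went from 170 to 83.2 CPM (-1.03 ± 0.19, adjusted p = 0.016), mt-Tl1 from 87.9 to 56.9 CPM (-0.62 ± 0.09, adjusted p = 0.0032) and mt-Tp from 74.3 to 54.3 CPM (-0.45 ± 0.07, adjusted p = 0.0013), whereas mt-Te did not pass (0.09 ± 0.08, adjusted p = 0.52). Of the 7 abundant protein-coding genes mt-Nd4, mt-Nd5 and mt-Cytb rose, and the range over the 7 was -0.09 to 0.24. The split did not follow length throughout: mt-Co3, of 784 bases and 9.17 CPM in WT, fell (-0.45 ± 0.12, adjusted p = 0.025), and mt-Atp8, of 204 bases, did not pass (0.18 ± 0.30, adjusted p = 0.78). Both were scarce, with mt-Atp8 at 0.753 CPM in WT, as were mt-Co2 (2.55 CPM) and mt-Atp6 (2.41 CPM), against 20753 CPM for mt-Co1. They therefore say little on length. Whether their counts, or those of mt-Nd3 and mt-Nd4l, follow the transcripts was not tested.

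The hypothesis that the mutant hearts were at an earlier stage of maturation was tested on 12 log2 ratios of mature to immature isoforms. At an adjusted p under 0.05 by exact permutation, 0% of the ratios were lower, and none was higher. The ratios of Cox6a2 to Cox6a1 (-0.27), Cox8b to Cox8a (-0.32) and Hk2 to Hk1 (-0.46) were lower without overlap, and those of Ckm to Ckb (0.36), Cacna1c to Cacna1h (0.15) and Ldhb to Ldha (0.26) were higher without overlap (exact permutation p = 0.029 each, adjusted p = 0.057). At this number of libraries no single ratio could pass alone after adjustment over the 12, so the lack of a call in either direction decides nothing and the hypothesis stays open.

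Ddx3y, also Y-linked, was at 35.5 CPM in WT replicate 4 and from 70.3 to 80.4 CPM in the other 7 libraries, while Xist lay between 1.252 and 1.979 CPM in all 8.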
